A study of Caenorhabditis elegans with 10 samples.

How the data were processed

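RNA was measured in whole Caenorhabditis elegans. Per the labels, each of the 10 samples was a pool of 80 to 100 worms at the L4 larval and young adult stages, grown at 21 °C, from which 600 ng of total RNA was labelled with Cy3 and hybridised to a 1-colour Agilent array. Mutants carried hpl-1(tm1624), hpl-2(tm1489) or his-24(ok1024), with 2 arrays each, and wild-type N2 worms gave 4 arrays. The 10 arrays lay on 4 slides. Slides 1 and 4 each held an hpl-1 and a wild-type array, and slides 2 and 3 each held an hpl-2, a his-24 and a wild-type array. The labels do not say that a replicate number marks a shared culture, day or batch.

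Per the file headers, the images were read with Agilent Feature Extraction 9.5.3.1. The processed signal of a spot is an intensity after the software's background subtraction and detrending within the array, per the file headers, with a surrogate value where the signal was too low. Raw mean signals and local backgrounds are intensities too, per the file headers. Other columns used here are the software's 0 or 1 marks for spots well above background, saturated or outlying, which are of another kind than a signal, per the file headers. The deposited series matrix holds log2 values. These had the same rank order as the median signal of each array (Spearman correlation 1 on all 10 arrays) and column medians of 9.6253 to 9.62592, so they are a log2 median signal with quantile normalization between arrays and no background subtraction. They are not centred on a gene or on a group, and higher means more signal. The notes of the authors name limma for this step, and its version and settings are not given in the sources used here. The genome build behind the probe positions is not given in the sources used here, so positions are those of the array files. Gene symbols came from the RefSeq annotation of WBcel235 by sequence name.

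Each array held 42964 spots of non-control probes and 1417 control spots. Spots with an outlier mark were left out on that array, which concerned 1162 spots on at least 1 array, and the remaining spots of a probe were averaged on the log2 scale. Of 20401 probes, 19115 named 1 gene, 722 named several genes and 564 named none. Only probes of 1 gene were used for gene tests, and 18215 genes had such a probe. The main values were log2 processed signals minus the 75th percentile of the non-control probes on the same array. A probe entered the tests where it was well above background on at least 2 arrays, the size of the smallest group. A gene with several probes was represented by the probe with the highest mean over the 10 arrays. This left 14972 genes, and 3243 genes were removed.

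The tools were R 4.3.3, limma 3.58.1 and data.table (version 1.17.8). A linear model with 1 mean per group was fitted to all 10 arrays with limma, with empirical Bayes moderation (6 residual and 2.45 prior degrees of freedom), and 6 contrasts were tested: each mutant against wild type and each mutant against each other mutant. The p-values were adjusted within each contrast by the Benjamini-Hochberg method, with a threshold of 0.05. All 4 groups share 1 estimate of the spread per gene because the mutants had 2 arrays each. An error printed as SE is the moderated standard error of the difference, and an SD is over the arrays of 1 group. The number of arrays limits the precision.

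Where no array of 1 group was well above background for a gene, its fold change was given as a bound ("at least N-fold"). The bound sets the mean of the brighter group against the dim group, whose arrays were raised to the lowest log2 signal that was well above background on that array wherever the gene lay under it. Where both groups were dim, no fold was given, but such genes stayed in the counts of genes and list members.

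A total of 32 gene lists from textbook knowledge of the worm (immune effectors, stress and detoxification genes, cuticle, tissue and germline markers, chromatin and small RNA genes, metabolism, F-box families and ribosomal proteins) was compared with all other genes by camera of limma. The preset correlation between genes was 0.01, and the test was repeated with a correlation estimated from the residuals. The p-values were adjusted over the 32 lists of a contrast. Members past the threshold were counted with p-values adjusted over all genes tested and, separately, adjusted over the list alone. In all, 8 list names had no match among the symbols (daf-21, ram-4, opt-2, mut-2, dod-1, dod-2, dod-8 and gei-7). Of the 1482 list genes, 24 belonged to more than 1 list, among them 13 of the 20 targets of the insulin-pathway transcription factor DAF-16 and 7 of the 19 intestine markers.

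Genes were named by a rule: the 3 targeted genes; for each mutant the 12 genes up and the 12 down with the largest absolute log2 fold change past the threshold and with every mutant array on the same side of every wild-type array; for each list up to 4 members with the largest change past the threshold, or else up to 2 with the smallest p; the 10 genes with the largest mean change in the same direction in all 3 mutants; and 5 up and 5 down between each pair of mutants. Neighbours of the targeted genes were examined outside this rule. A gene without a symbol was given its sequence name.

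Overlap between mutants was set against a simulation of unchanged groups that share the real wild-type arrays (50 draws), against independent lists, and against fits in which the mutants were compared with separate pairs of wild-type arrays. The alternatives were background correction by normexp with an offset of 50 followed by quantile normalization or by the 75th percentile, quantile normalization of the processed signal, scaling by the array median, the deposited matrix, no filter on dim probes, probes well above background on all 10 arrays, the mean over the probes of a gene, slide as a fixed or a random block, differences within a slide, the replicate number as a block, only the arrays of the mutant and wild type, an intensity trend in the empirical Bayes step, a threshold of at least 2-fold in addition, and the omission of each array. The groups, the tests, the lists, the naming rule and these alternatives were fixed before the data were examined; an alternative that averages the 4 wild-type arrays into 1 sample was added later.

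The fit was tested on simulated data with 14972 genes. Of 67 genes simulated with a log2 change of 1, 59 were recovered in hpl-1, 64 in hpl-2 and 63 in his-24. At a log2 change of 0.5 the numbers were 44, 46 and 50 of 67. Among 14772 unchanged genes, 7, 14 and 10 were called. Far fewer genes were changed in the simulation than were called in the data, and its noise was independent between genes and arrays. These rates therefore do not give the number of false calls or the recovery in the data. Probes of several genes and probes without a gene name were left out of the gene tests and are counted separately.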

Results

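Transcripts of whole worms were compared between hpl-1, hpl-2 and his-24 mutants (n = 2 arrays each) and the wild type (n = 4). HPL-1 and HPL-2 are heterochromatin protein 1 homologues, which bind methylated histone H3, and HIS-24 is a linker histone. The series asks what these chromatin proteins do to the expression of innate immune and stress genes. On each array 74.6% to 80.3% of the spots were well above background, and 14972 genes were tested. Arrays of the wild type correlated with each other across probes at 0.998 to 0.9987, and with mutant arrays at 0.9583 to 0.9762. Between arrays of 1 group, the variance of the difference was 1.46 to 5.55 times that of the noise between spots of a probe. The p-values rest on this spread, and whether it holds the variation between separate cultures was not tested. Larvae and young adults were mixed in the pools. A difference in age or culture between groups therefore cannot be told apart from the genotype in any contrast. The number of arrays limits the precision of every value.

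The signal of the his-24 probe was lost from his-24 mutants. Its probe (chromosome X, 14490949 to 14491008, build not given) fell from a log2 signal of −0.29 ± 0.11 relative to the 75th percentile of the array (SD, n = 4) to −9.01 ± 0.055 (SD, n = 2), which was not well above background on either array. This signal was thus at least 258-fold lower (adjusted p = 4.49e-10). The hpl-2 signal was lowered but present in hpl-2 mutants. The probe of isoform K01G5.2b (chromosome III, 10752178 to 10752237) fell from 1.37 ± 0.028 to 0.38 ± 0.22, by a log2 fold change of −0.99 (SE 0.0829, adjusted p = 1.11e-05). The probe of isoform K01G5.2a (chromosome III, 10753548 to 10753607) differed by −1.36, and a probe shared by hpl-2 and a pair of other genes differed by −0.91. The hpl-1 signal was not lower in hpl-1 mutants. Its only probe (K08H2.6, chromosome X, 13246821 to 13246880) read −0.43 ± 0.022 against −0.57 ± 0.046 in wild type, a difference of 0.14 that did not pass (adjusted p = 0.0813). The positions of the 3 deletions relative to the probes are not given in the sources used here, so a lost signal does not show that the whole transcript was lost, and the hpl-1 probe does not check the genotype. The hpl-1 transcript rose by 0.31 in his-24 mutants (adjusted p = 0.00221) and by 0.19 in hpl-2 mutants (adjusted p = 0.0198), and the his-24 transcript fell by 0.36 in hpl-1 mutants (SE 0.101, adjusted p = 0.0149).

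**Figure D1:**
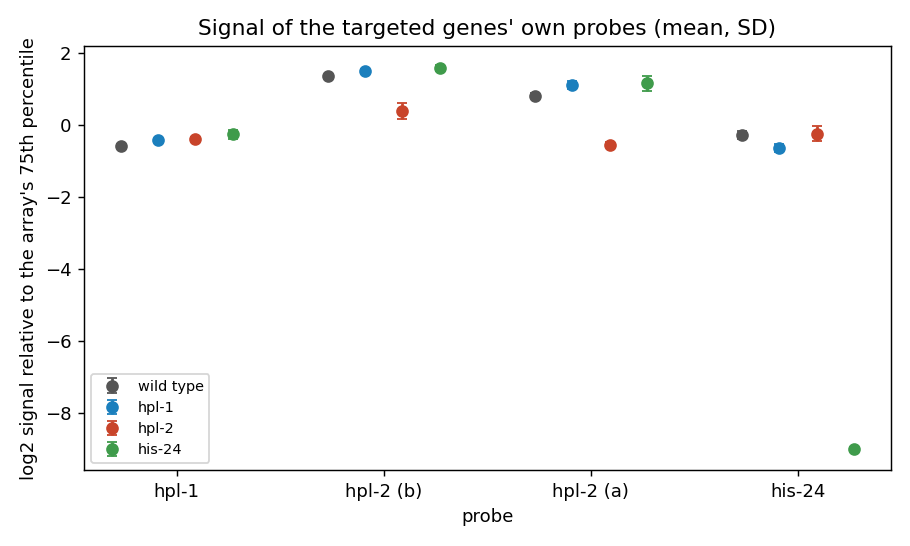
Log2 signal relative to the 75th percentile of the array (y axis) for the probes of hpl-1, hpl-2 (isoforms b and a) and his-24 (x axis). Colours mark the groups, points are group means and bars are the SD over arrays (n = 4 wild type, n = 2 per mutant). The his-24 probe lies at −9.01 in his-24 mutants against −0.29 in wild type, while the hpl-1 probe lies at −0.43 in hpl-1 mutants against −0.57.

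The first comparison asked which immune and stress genes depend on HPL-1. Genes induced by bacterial infection rose in hpl-1 mutants, while antimicrobial peptides and lysozymes fell. Of 18 infection response genes, 16 rose and 2 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.54 to 1.62 within slides. The secreted infection marker sysm-1 rose from −3.19 ± 0.017 (SD, n = 4) to 1.92 ± 0.086 (SD, n = 2), by 5.11 (SE 0.0621, adjusted p = 3.71e-10), irg-5 rose by 4.42, F55G11.8 by 3.62 and dod-24 by 2.71. The list shifted upward (camera adjusted p = 4.38e-08, adjusted p = 0.235 with an estimated correlation). Among 18 antimicrobial peptide genes of the nlp and cnc families, which the epidermis secretes, 13 fell and 3 rose, with a median of −1.01 (adjusted p = 0.000185, adjusted p = 0.381 with an estimated correlation). The peptide gene nlp-32 was at least 7.39-fold lower. Of 14 lysozymes, 9 fell and 4 rose (median −0.65), with ilys-3 at −3.39, ilys-6 at −3.05 and lys-6 at −2.67. Their shift passed (adjusted p = 0.0309, adjusted p = 0.567 with an estimated correlation, and 0.0804 under quantile normalization in a range of 0.0155 to 0.0804 over the alternatives). C-type lectins went both ways, with 47 of 139 higher and 44 lower (49 and 44 adjusted over the list alone, list adjusted p = 0.849): clec-4 rose by 4.34 and clec-9 fell by 6.42, being well above background on 1 of the 2 mutant arrays. Caenopores and antibacterial factors, counted as 1 list, also split, 9 higher and 7 lower of 23 (list adjusted p = 0.849), with abf-2 at 2.48 and spp-20 at −2.82.

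Stress genes split within their lists in hpl-1 mutants. The small heat shock genes hsp-16.2 and hsp-16.41 rose by 3.27 and 1.88, hsp-12.3 and hsp-12.6 fell by 2.63 and 1.49, and in all 5 of 22 heat shock genes rose and 10 fell (list adjusted p = 0.14). The superoxide dismutase gene sod-3 rose by 1.76 and the metallothionein gene mtl-1 fell by 1.92, among 10 higher and 4 lower of 26 oxidative stress genes (list adjusted p = 0.292). Of the DAF-16 targets, which the insulin pathway restrains, 11 of 20 fell and 3 rose, with a median of −0.42 (adjusted p = 0.0165, adjusted p = 0.398 with an estimated correlation, and 0.108 under quantile normalization in a range of 0.00985 to 0.108). Among 61 UDP-glucuronosyltransferases, which conjugate xenobiotics, 29 fell and 18 rose (30 and 18 adjusted over the list alone), with a median of −0.24 (adjusted p = 0.0267, adjusted p = 0.448 with an estimated correlation). Their member ugt-15 was at least 24.4-fold lower. Cytochrome P450 genes did not shift as a list (20 higher and 29 lower of 64, adjusted p = 0.137), although cyp-14A4 rose by 4.03 and cyp-34A10 fell by 3.83. Glutathione S-transferases counted 19 higher and 8 lower of 44 (21 and 8 adjusted over the list alone), gst-38 rose by 3.57, and the list missed the threshold at an adjusted p of 0.0522 (0.0158 to 0.193 over the alternatives, 0.0484 with slide as a block, and 0.0158 without hpl-1 replicate 2, 0.0475 without wild type replicate 1 and 0.0396 without either his-24 array).

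Cuticle genes rose in hpl-1 mutants. Of 143 cuticle collagens, 82 rose and 24 fell (82 and 26 adjusted over the list alone), with a median of 0.62 and 0.59 to 0.62 within slides. The collagen genes col-88 and col-128 rose by 3.56 and 3.24, and col-137 rose by 6.71, being well above background on 3 of the 4 wild-type arrays. The collagen shift passed (camera adjusted p = 4.29e-06, adjusted p = 0.39 with an estimated correlation). Hedgehog-related genes encode secreted proteins of epidermal and glial cells, and 39 of 54 rose and 7 fell, with a median of 0.80 (adjusted p = 7.78e-08, adjusted p = 0.0523 with an estimated correlation). Among them grl-19 was at least 24.9-fold higher, grl-23 at least 14.3-fold, and grd-6 and grl-3 rose by 3.71 and 2.90. F-box and MATH-BTB genes, which supply adaptors of ubiquitin ligases, counted 152 higher and 38 lower of 326 (153 and 38 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.000989, adjusted p = 0.235 with an estimated correlation). Linker histones fell, 6 of 9 with 1 higher, led by hil-7 at −2.06 and hil-1 at −1.04 (adjusted p = 0.0309, adjusted p = 0.343 with an estimated correlation, and 0.154 to 0.169 under quantile normalization, normexp with quantile normalization and the deposited matrix, in a range of 0.0196 to 0.169). The uncharacterised gene F56A4.3 was at least 748-fold higher than in wild type, where none of the 4 arrays was well above background. The largest decreases included vmo-1, at least 98.3-fold lower, the acyl-CoA synthetase acs-2, which fell by 5.44 (SE 0.0665, from 2.90 ± 0.035 to −2.54 ± 0.12, adjusted p = 3.71e-10), the lipase lipl-3 at −5.08 and the arginine kinase argk-1 at −4.99.

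In total 8079 genes (54%) differed between hpl-1 mutants and wild type, 4359 higher and 3720 lower, of which 854 and 532 did so by at least 2-fold. With slide as a block the number was 5735. Without slide 15 of the 32 lists shifted and with slide as a block 16.

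The second comparison asked the same of HPL-2. Genes of the intracellular pathogen response, which worms induce on infection by microsporidia or virus, rose together in hpl-2 mutants. Of 34 such genes tested, 31 rose and none fell (limma, 31 and 0 adjusted over the list alone), with a median log2 fold change of 3.18, of 2.97 with dim genes at their bound, and of 3.07 to 3.29 within slides, and of 1.23 over probes well above background on all 10 arrays. The filter could let in members well above background on the hpl-2 arrays alone, and it left out members dim on all arrays. It therefore favoured rising members in this count. The pals family members pals-29, pals-2 and pals-7 were at least 88.5-fold, 69.9-fold and 46.4-fold higher, and F26F2.4 at least 57.2-fold. The list passed with a camera adjusted p of 4.44e-14, with an adjusted p of 0.00553 with an estimated correlation, and with an adjusted p of 5.16e-15 with slide as a block. The infection response genes rose as well, 15 of 18 with 3 lower, by a median of 1.01 (adjusted p = 4.68e-05, adjusted p = 0.41 with an estimated correlation), including sysm-1 at 4.36 (SE 0.0621, adjusted p = 3.92e-10), irg-5 at 2.61 and F20G2.5 at 1.64. Antimicrobial peptides fell, 11 of 18 with 3 higher (median −0.61), and cnc-1 was at least 14.7-fold lower. Their list call was marginal (adjusted p = 0.0435, adjusted p = 0.707 with an estimated correlation), in a range of 0.0148 to 0.323 over the alternatives. It ended without wild type replicate 1 (adjusted p = 0.0616) and with normexp and the 75th percentile (adjusted p = 0.0586). It also ended over probes well above background on all 10 arrays (adjusted p = 0.323, median −0.33). Without hpl-2 replicate 1 the median was −0.62. Lysozymes went both ways, 8 lower and 6 higher of 14 (list adjusted p = 0.283), with ilys-3 and ilys-6 at −5.28 and −4.81. Among C-type lectins 59 rose and 51 fell of 139 (60 and 51 adjusted over the list alone, list adjusted p = 0.379), with clec-44 at least 62.4-fold higher and clec-258 at least 14.9-fold lower. Caenopores and antibacterial factors counted 10 higher and 6 lower of 23 (list adjusted p = 0.533), with spp-7 at −2.58 and spp-31 at −1.44.

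**Figure D2:**
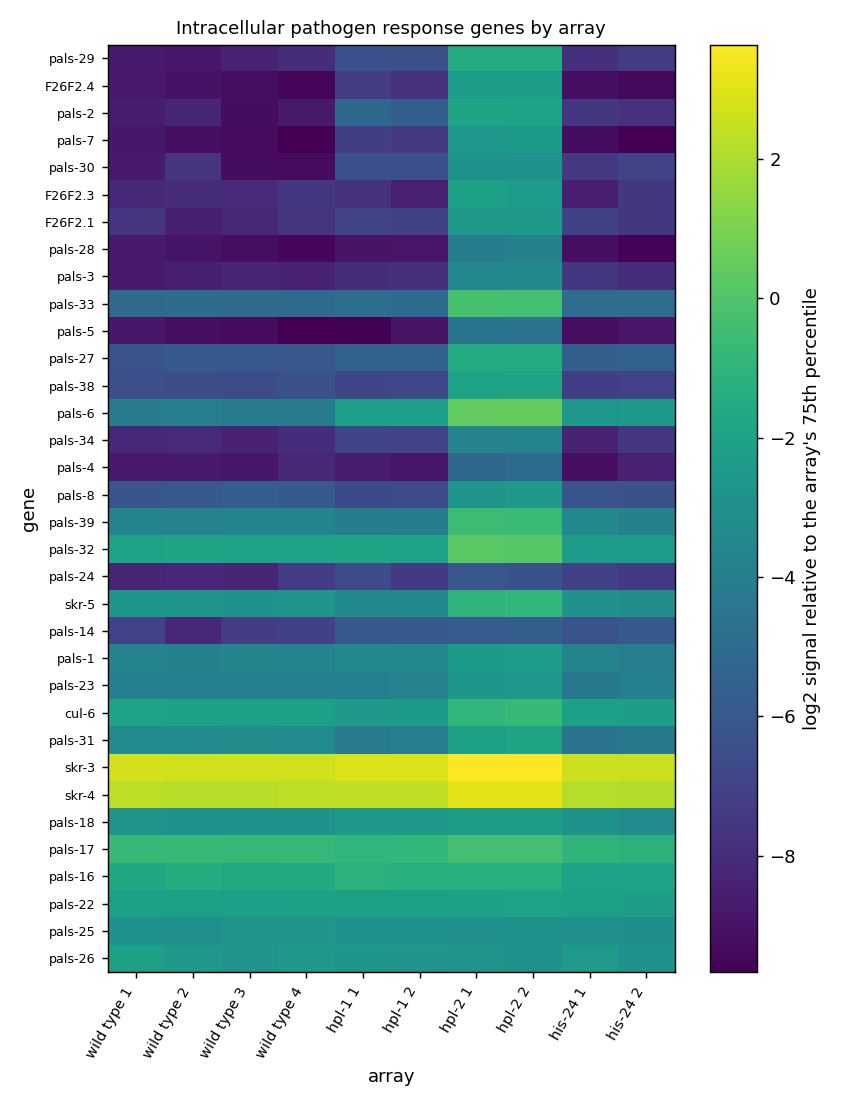
Heat map of 34 genes of the intracellular pathogen response (y axis) on the 10 arrays (x axis, grouped by genotype); the colour is the log2 signal relative to the 75th percentile of the array. In hpl-2 mutants 31 of the genes lie above wild type past the threshold, against 16 in hpl-1 and 8 in his-24 mutants.

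F-box and MATH-BTB genes formed the other large rising family in hpl-2 mutants. Of 326 genes, 220 rose and 31 fell (221 and 31 adjusted over the list alone), with a median of 0.59, and fbxa-75, fbxa-7, fbxa-136 and math-5 were at least 28.5-fold, 25.8-fold, 20.4-fold and 20-fold higher. Here too the filter could let in genes well above background on the hpl-2 arrays alone. The shift passed with both settings of camera (adjusted p = 1.48e-13, adjusted p = 0.0172 with an estimated correlation). The list of synMuv B and heterochromatin genes did not shift (10 higher and 7 lower of 35, adjusted p = 0.406), but lin-15B, lin-15A and lin-8 rose by 1.27, 1.09 and 0.76. Small RNA pathway genes did not shift either (17 higher and 11 lower of 46, adjusted p = 0.476), while the RNA-dependent RNA polymerase rrf-2 rose by 3.07 (SE 0.0746, adjusted p = 6.63e-09). Heat shock genes counted 5 higher and 13 lower of 22 (list adjusted p = 0.453), with hsp-16.2 at 3.62, hsp-16.41 at 2.18 and hsp-70 at 1.79. Oxidative stress genes counted 7 higher and 7 lower of 26 (list adjusted p = 0.923), with sod-3 at 2.22 and the thioredoxin trx-5 at least 8.44-fold higher. The metallothionein genes mtl-2 and mtl-1 fell by 1.65 and 1.48. Linker histones counted 2 higher and 6 lower of 9 (list adjusted p = 0.457), with hil-7 at −1.33. Among the lower genes, hil-8 was not well above background on any hpl-2 or wild-type array. Detoxification genes fell: 37 of 64 cytochrome P450 genes (38 adjusted over the list alone) with 15 higher, median −0.35 (adjusted p = 0.00596, adjusted p = 0.132 with an estimated correlation), and 39 of 61 UDP-glucuronosyltransferases with 12 higher, median −0.53 (adjusted p = 0.000814, adjusted p = 0.398 with an estimated correlation). Examples were cyp-33D3 at −4.23 and ugt-25 at −2.57. Glutathione S-transferases did not shift (11 higher and 23 lower of 44, adjusted p = 0.283), with gst-33 at −2.76.

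Single genes with large decreases in hpl-2 mutants included the delta-9 desaturase fat-7, which fell by 4.99 (SE 0.0542, adjusted p = 1.19e-10, n = 2 against n = 4 arrays), and argk-1, lipl-3 and acs-2, which fell by 6.08, 6.32 and 4.30. The flavin monooxygenase gene fmo-2 was at least 46.6-fold lower. A total of 9731 genes (65%) differed from wild type, 4480 higher and 5251 lower, of which 1197 and 870 did so by at least 2-fold. The higher group held 222 genes that were dim on every wild-type array. With slide as a block 7855 genes passed. Without slide 11 of the 32 lists shifted and with slide as a block 12.

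The third comparison asked what depends on the linker histone HIS-24. The infection response genes rose again, 15 of 18 with 3 lower, by a median of 1.13, while lysozymes and fungus-induced genes fell. The infection marker dod-24 rose from 0.85 ± 0.029 (SD, n = 4) to 4.39 ± 0.13 (SD, n = 2), by 3.54 (SE 0.0595, adjusted p = 1.27e-09), sysm-1 rose by 4.23, irg-5 by 4.01 and F55G11.8 by 2.94. The list shift passed (camera adjusted p = 1.57e-06, adjusted p = 0.224 with an estimated correlation, and 2.67e-06 with slide as a block). Of 14 lysozymes, 9 fell and 2 rose, with a median of −1.32 (adjusted p = 0.0045, adjusted p = 0.514 with an estimated correlation), led by ilys-3 at −5.06, ilys-6 at −3.89 and lys-6 at −3.70. Of 20 fungus-induced genes, 17 fell and 1 rose, with a median of −0.58 (adjusted p = 0.0022, adjusted p = 0.514 with an estimated correlation), such as fip-1 at −2.23 and fipr-17 at −1.69. These genes did not shift in hpl-1 mutants (5 higher and 6 lower, adjusted p = 0.483) or in hpl-2 mutants (1 higher and 8 lower, adjusted p = 0.236). Antimicrobial peptides counted 11 lower and 4 higher of 18, with cnc-1 and nlp-32 at least 14.2-fold and 8.2-fold lower. Their list adjusted p was 0.0599, with 0.00353 to 0.402 over the alternatives, and the median was −0.88 without his-24 replicate 1. The list passed as lower under quantile normalization (adjusted p = 0.00761) and normexp with quantile normalization (0.00397). It also passed after scaling by the array median (0.013) and in the deposited matrix (0.00353). C-type lectins counted 42 higher and 59 lower of 139 (43 and 60 adjusted over the list alone, list adjusted p = 0.633), with clec-9 at least 113-fold lower, and caenopores and antibacterial factors 6 higher and 12 lower of 23 (list adjusted p = 0.239), with spp-20 at −3.12. The intracellular pathogen response genes did not shift in his-24 mutants (8 higher and 7 lower of 34, adjusted p = 0.863) or in hpl-1 mutants (16 higher and 6 lower, adjusted p = 0.161), although pals-6 rose in both, by 1.53 and 1.92.

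Germline, chromatin and small RNA genes rose modestly in his-24 mutants. Of 32 oocyte and germline markers, 18 rose and none fell (limma, 18 and 0 adjusted over the list alone), with a median of 0.19, a call that passed under each scaling (adjusted p = 0.000313, adjusted p = 0.191 with an estimated correlation). The RNA-binding protein genes mex-1, mex-6 and gld-1 rose by 0.98, 0.68 and 0.64. Of 35 genes in the synMuv B and heterochromatin list, which also holds synMuv A genes and the growth factor gene lin-3, 20 rose and 2 fell, with a median of 0.20 (adjusted p = 0.000183, adjusted p = 0.205 with an estimated correlation), including the synMuv A gene lin-56 at 0.61, lin-3 at 0.44 and the chromatin remodeller gene let-418 at 0.42. Of 46 small RNA pathway genes, 32 rose and 5 fell, with a median of 0.24 (adjusted p = 6.03e-05, adjusted p = 0.205 with an estimated correlation), including dcr-1 at 0.83 and drh-1 at 0.77. Over the alternatives the medians ran from 0.18 to 0.39 for the oocyte and germline list. They ran from 0.19 to 0.40 for the synMuv B and heterochromatin list and from 0.22 to 0.44 for the small RNA list. Whether a smaller share of somatic tissue in the his-24 pools also gave these rises was not tested, so they may not be separate results. Among linker histones hil-7 fell by 2.91 and hil-1 by 0.85, with 2 higher and 4 lower of 9 (list adjusted p = 0.51, his-24 itself included). The zinc finger gene ztf-14, the next gene after his-24 along the X chromosome, was at least 25.2-fold higher (adjusted p = 9.41e-07), and the next gene again, M163.1, fell by 0.69 (adjusted p = 0.000827, chosen after its value was seen).

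Detoxification genes fell in his-24 mutants, as did single cuticle genes. Cytochrome P450 genes counted 41 lower and 13 higher of 64 (42 and 13 adjusted over the list alone), with a median of −0.39 (adjusted p = 0.00173, adjusted p = 0.125 with an estimated correlation), and cyp-34A10 fell by 4.06. UDP-glucuronosyltransferases counted 39 lower and 11 higher of 61 (40 and 11 adjusted over the list alone), with a median of −0.43 (adjusted p = 0.00455, adjusted p = 0.433 with an estimated correlation), and ugt-15 was at least 16.8-fold lower. The collagen genes col-74, dpy-14 and col-121 fell by 6.22, 4.59 and 4.08 and the cuticle gene cut-3 by 5.96, although collagens did not shift as a list (36 higher and 63 lower of 143, 36 and 64 adjusted over the list alone, adjusted p = 0.499). They did not shift in hpl-2 mutants either (50 higher and 67 lower, 50 and 70 adjusted over the list alone, adjusted p = 0.907). Hedgehog-related genes did not shift in his-24 mutants (17 higher and 24 lower of 54, 17 and 25 adjusted over the list alone, adjusted p = 0.93) or in hpl-2 mutants (22 higher and 19 lower, adjusted p = 0.393). Single members still rose strongly in hpl-2 mutants, where grl-23, grl-25 and grl-19 were at least 56.2-fold, 21.7-fold and 14.4-fold higher than in wild type. The rise of grl-23 and grl-19 was thus not limited to hpl-1 mutants. Heat shock genes counted 1 higher and 11 lower of 22, with hsp-70 at −1.95. Their list adjusted p was 0.0609, with 0.0418 to 0.138 over the alternatives, 0.0418 with slide as a block and 0.0469 without his-24 replicate 1. DAF-16 targets counted 3 higher and 11 lower of 20, with a median of −0.40 (adjusted p = 0.0396, adjusted p = 0.514 with an estimated correlation). This call ended without his-24 replicate 2 (adjusted p = 0.13) and without wild type replicate 1 (adjusted p = 0.0519), in a range of 0.0122 to 0.13. In hpl-2 mutants DAF-16 targets counted 5 higher and 11 lower (6 and 11 adjusted over the list alone, list adjusted p = 0.257). Glutathione S-transferases (13 higher and 17 lower of 44, adjusted p = 0.842), oxidative stress genes (7 higher and 5 lower of 26, adjusted p = 0.341) and F-box and MATH-BTB genes (96 higher and 123 lower of 326, 96 and 124 adjusted over the list alone, adjusted p = 0.849) did not shift in his-24 mutants, where gst-38 rose by 3.88 and sod-3 by 1.58.

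A total of 9115 genes (60.9%) differed between his-24 mutants and wild type, 3918 higher and 5197 lower, of which 390 and 954 did so by at least 2-fold. The split depended on the scaling. Higher genes made up 43% of these calls, but 65.7% (6364 of 9694) after scaling by the array median, which moved the median of all genes to 0.14 from −0.057, and 55.9% to 56% after quantile normalization, normexp with quantile normalization or in the deposited matrix. With normexp and the 75th percentile the median of all genes was −0.11 and without the filter −0.12. With slide as a block 6991 genes passed. Without slide 13 of the 32 lists shifted and with slide as a block 15.

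Muscle and fatty acid genes fell in all 3 mutants. Of 19 muscle markers, all 19 fell in hpl-1 and hpl-2 mutants and 18 in his-24 mutants (19 adjusted over the list alone), with medians of −0.60, −0.70 and −0.56. The pharyngeal myosin gene myo-1 fell by 1.08 in hpl-1, by 1.22 in hpl-2 and by 1.64 in his-24 mutants. The adjusted p of the list was 3.6e-08, 8.54e-06 and 2.35e-05, and with an estimated correlation the adjusted p was 0.0183, 0.0172 and 0.0625. Fatty acid metabolism genes fell in 38, 46 and 37 of 65 cases (39, 47 and 38 adjusted over the list alone) with 13, 10 and 12 higher, by medians of −0.35, −0.55 and −0.32. Their adjusted p was 4.14e-05, 2.21e-06 and 0.00295 (with an estimated correlation adjusted p = 0.0523, 0.0172 and 0.125). The desaturase fat-5 fell by 2.61, 2.93 and 2.43, and the carnitine acyltransferase cpt-3, which brings fatty acids into mitochondria, by 4.81, 4.55 and 3.62. Intestine markers fell in 11, 13 and 16 of 19 cases with 1, 2 and 0 higher (limma, 2 higher in hpl-1 adjusted over the list alone), by medians of −0.28, −0.49 and −0.43. Their adjusted p was 0.00105, 0.0031 and 6.03e-05 (with an estimated correlation adjusted p = 0.107, 0.117 and 0.0796). In hpl-2 the intestine call ended under quantile normalization, normexp with quantile normalization and the deposited matrix (adjusted p = 0.0812, 0.0637 and 0.0673, in a range of 0.00118 to 0.0812). The transporter gene pgp-1 of the gut fell by 2.69, 2.76 and 1.97. The size of the falls depended on the processing. Over the alternatives the least negative medians in hpl-1, hpl-2 and his-24 were −0.50, −0.38 and −0.36 for muscle markers. They were −0.20, −0.29 and −0.12 for fatty acid genes and −0.13, −0.22 and −0.23 for intestine markers.

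**Figure D3:**
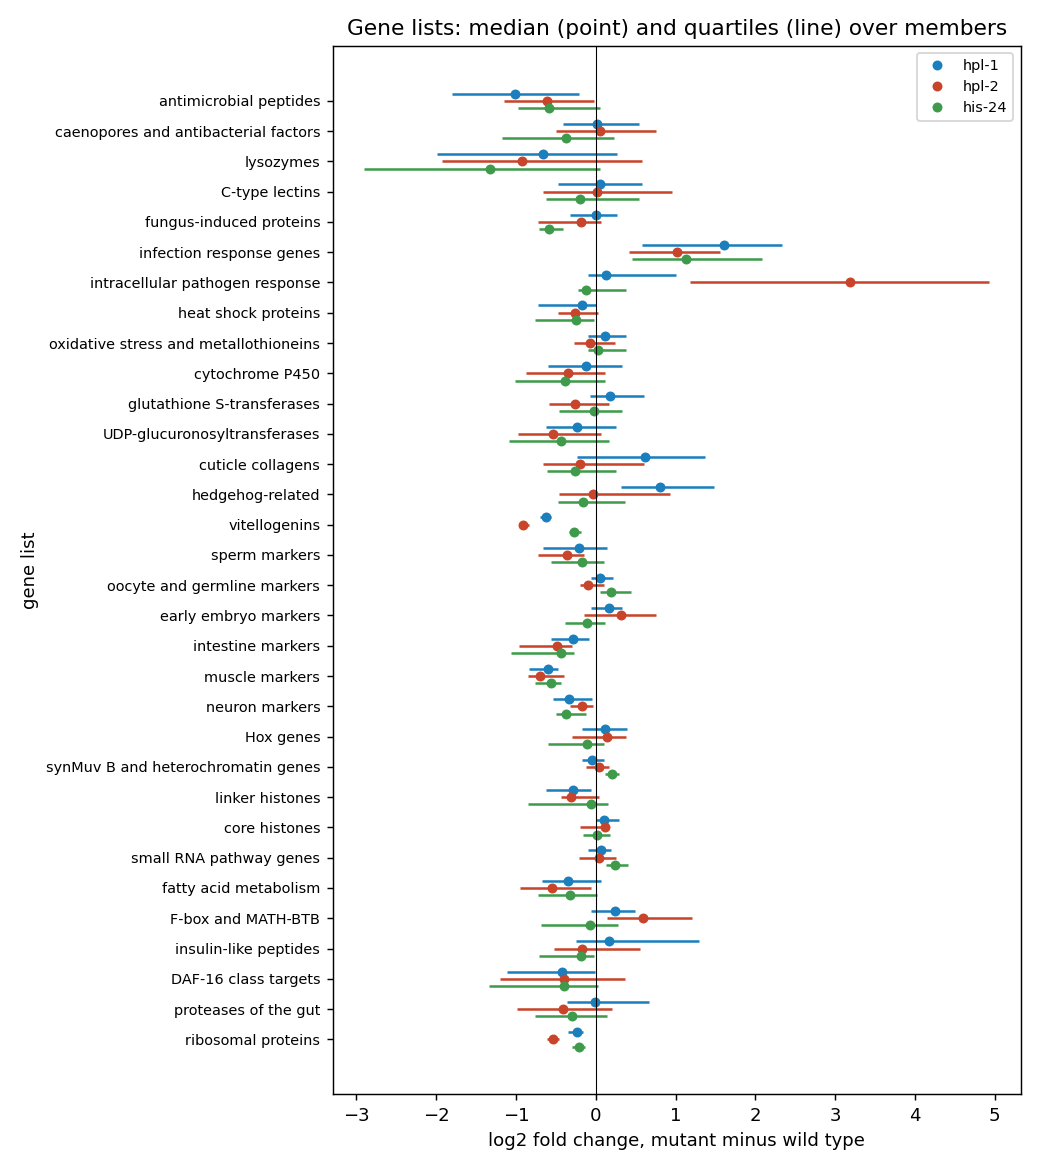
Log2 fold change of mutant minus wild type (x axis) for the members of 32 gene lists (y axis) in the 3 mutants; points are medians over the genes of a list and lines run from the lower to the upper quartile. The intracellular pathogen response lies at a median of 3.18 in hpl-2 mutants and muscle markers at −0.60, −0.70 and −0.56; the ribosomal protein medians of −0.24 and −0.54 in hpl-1 and hpl-2 turn positive under quantile normalization, normexp with quantile normalization and the deposited matrix.

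Neuron markers fell in hpl-1 mutants (16 of 25 with none higher by limma, median −0.33, adjusted p = 0.00017, adjusted p = 0.36 with an estimated correlation) and in his-24 mutants (17 lower and 2 higher, median −0.38, adjusted p = 0.00616, adjusted p = 0.506 with an estimated correlation), including unc-13 at −0.82 and −0.99. In hpl-2 mutants 11 fell and 1 rose (10 and 1 adjusted over the list alone) and the list did not pass (adjusted p = 0.104). Sperm markers fell in hpl-2 mutants (24 of 40 with 3 higher, median −0.36, adjusted p = 0.0031, adjusted p = 0.598 with an estimated correlation), where the major sperm protein gene msp-63 fell by 1.54. In hpl-1 mutants 18 fell and 5 rose (median −0.20, adjusted p = 0.0349, adjusted p = 0.538 with an estimated correlation). That call ended without hpl-1 replicate 2 (adjusted p = 0.0683), in a range of 0.0134 to 0.0683. In his-24 mutants 18 fell and 6 rose (list adjusted p = 0.241). Oocyte and germline markers counted 8 higher and 4 lower in hpl-1 (adjusted p = 0.488) and 6 higher and 8 lower in hpl-2 mutants (5 and 7 adjusted over the list alone, adjusted p = 0.822), but passed as higher under quantile normalization, normexp with quantile normalization and the deposited matrix (adjusted p = 0.0126 to 0.0171 in hpl-1 and 0.0159 to 0.0268 in hpl-2). Of the yolk protein genes in the vitellogenin list, only vit-1, vit-3 and vit-6 were in the gene tests, and vit-2, vit-4 and vit-5 were not. All 3 tested genes fell in hpl-1 and in hpl-2 mutants, such as vit-1 by 0.63 and 0.92, and 1 did in his-24 mutants. The list did not pass in hpl-1 (adjusted p = 0.0729, 0.0339 without either his-24 array, in a range of 0.0339 to 0.163), hpl-2 (adjusted p = 0.113) or his-24 (adjusted p = 0.546). Early embryo markers counted 6 higher and 1 lower of 16 in hpl-1, 9 and 4 in hpl-2, and 3 and 7 in his-24 mutants (adjusted p = 0.393, 0.122 and 0.51), with tbx-37 at 2.03 in hpl-2. The Hox gene lin-39 fell by 0.82, 0.84 and 0.92 in hpl-1, hpl-2 and his-24 mutants, while the 6 Hox genes as a list did not shift (adjusted p = 0.969, 0.843 and 0.499).

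Ribosomal protein genes shifted downward as a list in hpl-1 mutants (13 of 74 lower with none higher by limma, 6 adjusted over the list alone, median −0.24, adjusted p = 0.000185, adjusted p = 0.657 with an estimated correlation) and in hpl-2 mutants (67 of 74 lower, 70 adjusted over the list alone, median −0.54, adjusted p = 5.61e-07, adjusted p = 0.707 with an estimated correlation), but both medians turned positive, at 0.042 to 0.056 and 0.0085 to 0.013, under quantile normalization, normexp with quantile normalization and the deposited matrix (adjusted p = 0.506 to 0.561 and 0.885 to 0.893). Their direction therefore depends on the scaling. In hpl-2, rpl-18A and rps-2 differed by −0.85 and −0.81. In his-24 mutants 2 rose and 12 fell (0 and 5 adjusted over the list alone, adjusted p = 0.0599, 0.00963 with slide as a block, 5.08e-07 without his-24 replicate 1 and 0.0427 without wild type replicate 2, in a range of 5.08e-07 to 0.362). Core histones did not shift in any mutant (7 higher and 1 lower of 21 in hpl-1, 5 and 5 in hpl-2, 6 and 4 in his-24, adjusted p = 0.112, 0.734 and 0.487), although the hpl-1 list passed as higher in 3 of the scalings (adjusted p = 0.0279 to 0.0362). In hpl-1 mutants the synMuv B and heterochromatin genes (3 higher and 8 lower of 35, 2 and 8 adjusted over the list alone, adjusted p = 0.332) and the small RNA genes (10 higher and 7 lower of 46, 9 and 6 adjusted over the list alone, adjusted p = 0.614) did not shift, and lin-15B and lin-15A fell by 0.66 and 0.62. Insulin-like peptide genes did not shift against wild type (9 higher and 5 lower of 20 in hpl-1, 7 and 8 in hpl-2, 2 and 10 in his-24, adjusted p = 0.332, 0.907 and 0.117), and ins-35 rose by 2.17 and 2.00 in hpl-1 and hpl-2 mutants. Gut proteases did not shift in hpl-1 (20 higher and 17 lower of 51, adjusted p = 0.849), hpl-2 (14 and 30, adjusted p = 0.0674, 0.0417 with slide as a block, 0.0438 without the filter on dim probes and 0.0411 with the wild-type arrays as 1 sample) or his-24 mutants (11 and 26, adjusted p = 0.0739, 0.0454 without his-24 replicate 1, in a range of 0.0142 to 0.264), with cpr-1 at −2.48 in his-24. For some lists that did not pass, the median and the mean differed in sign. These were the caenopores and antibacterial factors, C-type lectins, fungus-induced genes and gut proteases in hpl-1 mutants. In hpl-2 mutants they were the heat shock, oxidative stress, collagen, hedgehog-related, Hox and insulin-like genes, and in his-24 mutants the intracellular pathogen response and glutathione S-transferase genes.

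Genes that changed the same way in all 3 mutants numbered 4007, of which 1795 were higher and 2212 lower. Unchanged groups simulated against the same wild-type arrays gave at most 1 such gene in 50 draws, which is chance with no effect in any mutant, and independent lists of the same sizes would give 341 higher and 453 lower. The secreted infection marker sysm-1 rose and argk-1, lipl-3, cror-2, vmo-1 and cpt-3 fell in all 3. The uncharacterised C07G1.7 was dim on every wild-type array and at least 22.6-fold, 240-fold and 59.2-fold higher in hpl-1, hpl-2 and his-24 mutants. The dehydrogenase gene cror-2 fell by 3.82 in hpl-1 and was at least 77.4-fold and 64.8-fold lower in hpl-2 and his-24 mutants. Pairs of mutants shared 5187 (hpl-1 and hpl-2), 5328 (hpl-1 and his-24) and 5686 (hpl-2 and his-24) genes with the same direction, against 989, 748 and 1051 with opposite directions. With each mutant of a pair set against its own 2 wild-type arrays, the shared genes were 3857 or 3738, 3854 or 3688 and 4319 or 4291, depending on which arrays went to which mutant. The covariance of the fold changes across genes was 0.341, 0.328 and 0.333, against 0.0052, 0.0051 and 0.0051 for unchanged groups that share the wild-type arrays. The correlation was 0.546, 0.673 and 0.542, against 0.331, 0.330 and 0.325 for these unchanged groups. Genes are not independent replicates. The simulated groups held noise only. A difference in culture or age between the wild-type pools and all mutant pools would also give shared genes, and it cannot be told apart here.

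The mutants were also compared with each other, to ask which responses differed between them. A difference in age or culture between the pools of 2 mutants would also give such differences, and it cannot be told apart here. Intracellular pathogen response genes were higher in hpl-2 than in hpl-1 mutants (27 of 34 with none lower by limma, 28 adjusted over the list alone, median 2.90, adjusted p = 1.14e-16, adjusted p = 0.00343 with an estimated correlation), as were F-box and MATH-BTB genes (187 higher and 46 lower, 195 and 49 adjusted over the list alone, median 0.42, adjusted p = 3.44e-11, adjusted p = 0.0428 with an estimated correlation). For both lists the filter could let in members well above background on the hpl-2 arrays alone, which favoured members higher in hpl-2. Lower in hpl-2 than in hpl-1 mutants were collagens (78 with 11 higher, 79 and 11 adjusted over the list alone, median −0.42, adjusted p = 3.46e-07, adjusted p = 0.576 with an estimated correlation) and hedgehog-related genes (36 with 9 higher, median −0.76, adjusted p = 0.000113, adjusted p = 0.186 with an estimated correlation). Glutathione S-transferases were lower too (28 with 6 higher, 29 and 6 adjusted over the list alone, median −0.47, adjusted p = 0.00047, adjusted p = 0.349 with an estimated correlation). The receptor gene sru-47 was at least 118-fold higher and fmo-2 at least 51.6-fold lower in hpl-2. In all 7543 genes differed, 3219 higher and 4324 lower in hpl-2, and 3772 did with slide as a block. The hpl-1 arrays shared no slide with those of hpl-2 or his-24, so this contrast and the next cannot be computed within a slide.

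Collagens and hedgehog-related genes were lower in his-24 than in hpl-1 mutants, 91 of 143 with 1 higher (92 and 1 adjusted over the list alone, median −0.79, adjusted p = 1.35e-13, adjusted p = 0.206 with an estimated correlation) and 40 of 54 with 3 higher (41 and 3 adjusted over the list alone, median −1.11, adjusted p = 1.8e-10, adjusted p = 0.0719 with an estimated correlation). The synMuv B and heterochromatin genes were higher in his-24 than in hpl-1 mutants (21 of 35 with none lower by limma, 22 adjusted over the list alone, median 0.23, adjusted p = 2.85e-08, adjusted p = 0.137 with an estimated correlation). Insulin-like genes were lower (13 of 20 with 1 higher, median −0.68, adjusted p = 0.000228, adjusted p = 0.137 with an estimated correlation). The gene F56A4.3 differed by −9.49, being well above background on 1 of the 2 his-24 arrays, and grl-19 was at least 29.7-fold lower in his-24. Here 6180 genes differed, 2061 higher and 4119 lower in his-24, and 2186 did with slide as a block. Higher genes were 33.4% of the calls, 66.4% after scaling by the array median (which put the median of all genes at 0.14), and 50.1% to 51.9% after quantile normalization, normexp with quantile normalization or in the deposited matrix.

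Between his-24 and hpl-2 mutants the intracellular pathogen response genes were lower in his-24 (30 of 34 with none higher by limma, 31 adjusted over the list alone, median −2.97, adjusted p = 1.66e-16, adjusted p = 0.00353 with an estimated correlation), and so were F-box and MATH-BTB genes (221 lower and 28 higher of 326, 224 and 30 adjusted over the list alone, median −0.74, adjusted p = 8.98e-16, adjusted p = 0.0175 with an estimated correlation). The filter favoured members higher in hpl-2 in these counts as well. Immune genes went in both directions: clec-3 and clec-2 were higher in his-24 by 5.21 and 4.81, and F26F2.4 was at least 68-fold lower. In this contrast 7618 genes differed, 3575 higher and 4043 lower in his-24, and 6150 did with slide as a block. Higher genes were 46.9% of the calls, 72.6% after scaling by the array median (which put the median of all genes at 0.24), and 56.7% to 57.2% after quantile normalization, normexp with quantile normalization or in the deposited matrix.

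Of the 96 list tests against wild type, 39 passed with the preset correlation and 5 with an estimated one. All 39 passed with slide as a block too, where the total was 43, and none passed when slide was a block and the correlation was estimated.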

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

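The tests on paralog probes, on the normalization, on muscle, intestine and fatty acid genes against neuron markers, on intestine and fatty acid genes against pairs of wild-type arrays, on the stage texts and on the hpl-1 arrays were chosen after the results were seen.

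In 15 of 260 named genes 1 of the 4 wild-type arrays stood apart, with a gap to the nearest array that made up 0.831 or more of the range (Dixon's Q test at 95%). Chance gives this in about 1 of 20 genes, which is close to the number found. Wild type replicate 4 was lowest for cyp-34A10 (0.952 of the range) and dct-7 (0.863) and highest for ins-22 (0.873). Wild type replicate 3 was highest for lin-13 (0.843), ugt-32 (0.924) and ZK218.5 (0.834) and lowest for lev-11 (0.834) and spp-7 (0.927). Wild type replicate 1 was lowest for C32H11.3 (0.955), pgp-1 (0.831) and gld-1 (0.866) and highest for lbp-8 (0.909). Wild type replicate 2 was highest for idpp-3 (0.841) and rrf-2 (0.836) and lowest for mex-3 (0.918).

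Probes outside the gene tests also differed from wild type by at least 2-fold past the threshold. Among 357 probes without a gene name these were 25 in hpl-1, 60 in hpl-2 and 33 in his-24 mutants. Among 609 probes that match several genes they were 94, 123 and 63.

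The rise of the intracellular pathogen response genes in hpl-2 mutants was weighed against technical causes. If the rise came only from pals probes reading each other's transcripts, members outside the pals family would stay near 0. Their median log2 fold change was 1.82. These few members were F26F2.1, F26F2.3, F26F2.4, cul-6, skr-3, skr-4 and skr-5, and they rose unevenly. F26F2.4 was at least 57.2-fold higher, while skr-3 read 3.63 and 3.64 on the hpl-2 arrays against 2.69 to 2.74 in wild type. Whether their own probes read each other's transcripts, and how many pals genes rose separately, was not tested. A rise shared by all genes dim in wild type was also excluded, since the list lay at the 100 percentile of 10000 random lists matched on the wild-type level. The lowest median over 5 other normalizations was 2.12, and it was 1.23 over probes well above background on all 10 arrays, which leaves out members dim in wild type. Loss of HPL-2 and an infection of the hpl-2 cultures both stay open, since no test here separates them.

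The fall of muscle, intestine and fatty acid genes in all 3 mutants was weighed next. A smaller share of all somatic tissue would lower neuron markers too, and these did fall in hpl-1 and his-24 mutants. Oocyte and germline markers rose in his-24 mutants and, under 3 of the scalings, in the others. Muscle markers fell further than neuron markers in each mutant (highest two-sided permutation p = 0.00265, 19 and 25 genes). The permutation shuffled genes between the lists, so this p does not measure variation between worm pools. An equal fall of all somatic markers would not give this difference. A smaller share stays open for muscle, since markers of different tissues need not fall equally with it. Intestine genes differed from neurons only in hpl-2 and his-24 mutants (permutation p = 0.031 and 0.0103, highest permutation p = 0.222, in hpl-1). Fatty acid genes differed from neurons only in hpl-2 mutants (permutation p = 0.0253, highest permutation p = 0.432, in hpl-1). For both lists a smaller somatic share cannot be told apart from a change of their own. Against either pair of wild-type arrays the muscle, intestine and fatty acid medians were −0.56, −0.30 and −0.30 or lower, so odd arrays within 1 pair do not explain the falls. A difference in culture or age between the wild-type pools and all mutant pools cannot be told apart from the genotypes, because 1 growth and stage text covers the 10 arrays and L4 larvae and young adults were mixed.

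The hpl-1 signal in the arrays labelled hpl-1 was 0.14 above wild type. An exchange with wild-type arrays is argued against by a highest correlation of 0.975 between an hpl-1 and a wild-type array, under the 0.998 of the least similar wild-type pair. An exchange with his-24 or hpl-2 arrays is argued against by the his-24 signal, which fell by 0.36 (adjusted p = 0.0149) but stayed well above background, and by the hpl-2 signal, which differed by 0.13 (adjusted p = 0.206) and not by −0.99 as in hpl-2 mutants. Whether the probe lies outside the deleted part cannot be told apart from a stable mutant transcript, since the position of the deletion is not given in the sources used here.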

How the results depend on the processing

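The alternative that averages the wild-type arrays into 1 sample was chosen after the results were seen, and the others were set before.

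Of 265 further values of the counts of changed genes, shared genes and list shifts, 245 stayed within 1.5 times the value in the text and 20 did not. With slide as a fixed block, which spends 3 of the 6 residual degrees of freedom, the differences between mutants fell to 3772 genes for hpl-2 against hpl-1 and 2186 for his-24 against hpl-1. With a threshold of at least 2-fold, which removes smaller changes by construction, 1386, 2067 and 1344 genes passed in hpl-1, hpl-2 and his-24 mutants. Between mutants 1623, 1047 and 1516 passed, for hpl-2 against hpl-1, his-24 against hpl-1 and his-24 against hpl-2. All 3 mutants then shared 468 genes and pairs of mutants 722, 667 and 711. With the wild-type arrays as 1 sample, which leaves fewer degrees of freedom, 3649, 5666 and 4505 genes passed against wild type and 4109 for his-24 against hpl-1. The shared genes were then 1600 in all 3 mutants and 2201, 2150 and 2598 in pairs. The number of lists that shifted ran from 36 to 45 of 96 over the alternatives.

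Of the values of named genes under the alternatives, 11334 kept their direction and their side of the threshold. Among these, 419 were differences within a slide, which were not tested and lay within 1 standard deviation between arrays. A further 274 no longer passed, 112 of them under the 2-fold threshold, while 19 newly passed and 6 changed sign. Of the values of lists, 2033 kept both, or for differences within a slide lay within 1 standard deviation between arrays, 15 no longer passed, 37 newly passed and 103 changed sign. A further 20 medians of differences within a slide lay outside that spread. The Hox gene mab-5 in his-24 mutants turned to 0.036 with normexp and quantile normalization, 0.022 under quantile normalization, 0.029 after scaling by the array median and 0.019 in the deposited matrix. The hpl-2 gene turned to −0.0069 between his-24 and hpl-1 mutants under quantile normalization. The cause was not tested.

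With normexp and quantile normalization the medians that changed sign in hpl-1 were −0.010 for C-type lectins, −0.0041 for fungus-induced proteins, −0.014 for Hox genes, 0.011 for synMuv B genes, 0.050 for gut proteases and 0.042 for ribosomal proteins. In hpl-2 mutants they were 0.10 for oxidative stress genes, 0.037 for cuticle collagens, 0.0081 for hedgehog-related genes, 0.20 for oocyte markers, 0.084 for linker histones and 0.0085 for ribosomal proteins. In his-24 mutants they were 0.061 for the intracellular pathogen response, 0.040 for glutathione S-transferases, 0.036 for vitellogenins, 0.070 for early embryo markers, 0.094 for Hox genes, 0.062 for linker histones, 0.086 for F-box and MATH-BTB genes, 0.025 for insulin-like peptides and 0.11 for ribosomal proteins. With normexp and the 75th percentile the medians that changed sign in hpl-1 were −0.11 for C-type lectins, −0.016 for fungus-induced proteins, −0.065 for Hox genes and 0.0024 for synMuv B genes. In hpl-2 mutants they were −0.077 for C-type lectins and −0.040 for Hox genes. Under quantile normalization of the processed signal the medians that changed sign in hpl-1 were −0.035 for C-type lectins, −0.0071 for fungus-induced proteins, 0.093 for gut proteases and 0.056 for ribosomal proteins. In hpl-2 mutants they were 0.11 for oxidative stress genes, 0.023 for cuticle collagens, 0.22 for oocyte markers, 0.061 for linker histones and 0.013 for ribosomal proteins. In his-24 mutants they were 0.056 for the intracellular pathogen response, 0.076 for glutathione S-transferases, 0.052 for vitellogenins, 0.080 for early embryo markers, 0.10 for Hox genes, 0.14 for linker histones, 0.10 for F-box and MATH-BTB genes, 0.00088 for gut proteases and 0.10 for ribosomal proteins. After scaling by the array median the medians that changed sign in his-24 were 0.0021 for C-type lectins, 0.079 for the intracellular pathogen response, 0.18 for glutathione S-transferases, 0.040 for hedgehog-related genes, 0.031 for sperm markers, 0.094 for early embryo markers, 0.10 for Hox genes, 0.14 for linker histones, 0.13 for F-box and MATH-BTB genes and 0.015 for insulin-like peptides. In the deposited matrix the medians that changed sign in hpl-1 were −0.00094 for C-type lectins, −0.0015 for fungus-induced proteins, −0.0029 for Hox genes, 0.021 for synMuv B genes, 0.023 for gut proteases and 0.046 for ribosomal proteins. In hpl-2 mutants they were 0.10 for oxidative stress genes, 0.042 for cuticle collagens, 0.0098 for hedgehog-related genes, 0.22 for oocyte markers, 0.065 for linker histones and 0.012 for ribosomal proteins. In his-24 mutants they were 0.060 for the intracellular pathogen response, 0.039 for glutathione S-transferases, 0.049 for vitellogenins, 0.067 for early embryo markers, 0.085 for Hox genes, 0.059 for linker histones, 0.079 for F-box and MATH-BTB genes, 0.033 for insulin-like peptides and 0.10 for ribosomal proteins. Without the filter on dim probes the medians that changed sign in hpl-1 were −0.076 for C-type lectins and −0.12 for fungus-induced proteins. In hpl-2 mutants it was −0.066 for C-type lectins. With probes well above background on all 10 arrays the median that changed sign in hpl-1 was −0.16 for Hox genes. In hpl-2 mutants they were −0.021 for C-type lectins and −0.026 for Hox genes. With slide as a fixed block the medians that changed sign in hpl-1 were −0.0098 for caenopores and antibacterial factors and −0.012 for fungus-induced proteins. With the replicate number as a block the median that changed sign in hpl-1 was 0.021 for gut proteases. In hpl-2 mutants it was 0.00055 for hedgehog-related genes. The cause of these changes was not tested, and of the lists concerned only ribosomal proteins in hpl-1 and hpl-2 mutants had passed in the text.

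Over the omission of each array, medians that changed sign ran from −0.00062 to 0.045 for caenopores and antibacterial factors in hpl-1, −0.0052 to 0.0063 for fungus-induced proteins in hpl-1, −0.060 to 0.10 for gut proteases in hpl-1, −0.022 to 0.11 for C-type lectins in hpl-2, −0.0047 to 0.10 for small RNA pathway genes in hpl-2 and −0.013 to 0.13 for oxidative stress genes in his-24. Others ran from −0.61 to 0.027 for vitellogenins in his-24, −0.20 to 0.084 for linker histones in his-24, −0.055 to 0.16 for core histones in his-24, −0.46 to 0.039 for ribosomal proteins in his-24 and −0.11 to 0.19 for the his-24 gene in hpl-2. The cause was not tested. Without 1 mutant array the other array of that group is assumed to vary like the other groups.

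Arrays of the same replicate number were checked for shared deviations from their group means. Between mutants these correlated at 0.2, 0.166 and 0.219 (hpl-1 with hpl-2, hpl-1 with his-24, hpl-2 with his-24), and between mutants and wild type from −0.26 to 0.0889, so not every array followed its own number. With replicate number as a block on the 8 arrays numbered 1 and 2, 5868, 7731 and 6908 genes passed in hpl-1, hpl-2 and his-24 mutants, and 6001, 7875 and 7033 without it. Of the list calls against wild type on these 8 arrays, the block changed only that of heat shock proteins in his-24 mutants (adjusted p = 0.0484 with it and 0.0537 without it). Antimicrobial peptides in his-24 mutants passed on these arrays with the block (adjusted p = 0.0316) and without it (0.0443).

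Lists were not run with slide as a random block, with an intensity trend or with the 2-fold threshold, and differences within a slide give values without a test. Signal over background limits the dim genes: 3243 genes were not tested, and changes of genes dim in a whole group are known only as bounds.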

Other observations

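The choice of genes next to the mutated loci, and the rule by which the test on chromosome arms was read, were set after the values were seen.

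The 5 genes on either side of each mutated locus were read as well. After his-24, ztf-14 was well above background on both his-24 arrays and on no array of hpl-1 or hpl-2 mutants or wild type, while gfi-3 on the other side of his-24 differed by −0.10 in his-24 mutants (adjusted p = 0.264). Near hpl-1, K08H2.5 rose by 1.65 in hpl-2 mutants (adjusted p = 5.54e-07) and differed by −0.11 in hpl-1 mutants (adjusted p = 0.313), and the cytochrome P450 gene cyp-14A1 rose by 1.76 in hpl-1, 0.68 in hpl-2 and 0.81 in his-24 mutants. Near hpl-2, dkc-1 fell by 0.46, 0.70 and 0.21 in the same order. The condensin-complex gene dpy-28, which takes part in dosage compensation of the X chromosomes, rose by 0.83, 0.82 and 1.06 (adjusted p = 0.000223, 0.000158 and 4.66e-05).

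Genes that changed against wild type and also differed from both other mutants numbered 2797 in hpl-1, 4278 in hpl-2 and 3078 in his-24 mutants.

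A hypothesis was that genes silent in wild type and switched on without HPL-2 lie on chromosome arms, where H3 methylated at lysine 9 is abundant. Arms were taken as the outer parts of each chromosome by gene order, a definition that by itself puts 66.7% of all genes on them. Of 3449 genes dim on every wild-type array, 225 were well above background on both hpl-2 arrays (counted as switched on, with no test of the change). Of these, 80.9% lay on chromosome arms, against 77.6% of those that stayed dim. The share was higher but not past the threshold (one-sided permutation p = 0.201 over 10000 circular shifts of gene order), and a small excess cannot be told apart from chance. The shares in hpl-1 and his-24 mutants were 70% (permutation p = 0.949) and 82.4% (permutation p = 0.356).

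Among 700 genes with several probes, 27 in hpl-1, 24 in hpl-2 and 11 in his-24 mutants had probes that passed in opposite directions.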
